A study of Macaca fascicularis with 2 samples.

How the data were processed

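Single-cell RNA was measured in 2 libraries of cynomolgus macaque blastoids, 1 labelled D7 and 1 labelled D17, made with the 10x 3′ v3.1 kit per the labels' protocols. Structures were picked by hand and parted with trypsin per the labels' protocols. The deposited values were counts of UMIs per gene and barcode, made with Cell Ranger 6.1.2 per the submitters' processing notes. The genome build and annotation behind the counts were not given in the sources used here. All values in the files were whole numbers. The lowest total of a listed barcode was 500 UMIs in both files. The D7 file listed 20680 genes, each seen in at least 3 barcodes, and the D17 file 28165, with all genes of D7 among them. The 7485 genes listed for D17 alone held 0.0205% of its UMIs and were left out of comparisons between the libraries. Of genes listed by locus number, 453 of 5570 in D7 and 721 of 11294 in D17 took a symbol from the reference table by gene number, and 5 older symbols were renamed. Names were assigned once over both files. No mitochondrial genes were listed, so no filter on them was possible.

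Cells were kept with at least 500 genes and 1000 UMIs. Scrublet, run in Scanpy 1.11.5, scored doublets (2 cells in 1 droplet), and its automatic threshold marked 1 cell in D7 and 0 in D17. Kept were 12485 cells with 38516073 UMIs and a median of 1282 genes in D7. In D17 these were 9945 cells with 90217210 UMIs and a median of 3006 genes. Counts were scaled to 10000 per cell and logged, 2000 variable genes and 30 components were taken, and cells were clustered per library with the Leiden method on 15 neighbours at a resolution of 0.5 (python-igraph 0.11.9, scikit-learn 1.9.0, random seed 0).

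Each cluster was scored on 12 marker lists. The excess of a marker was log2(CPM + 10) of the cluster's summed UMIs minus the mean over the library's clusters. The best list of a cluster was the list with most markers at an excess of at least 1, and ties went to the larger mean excess. A cluster took its name where at least 3 markers had such an excess and the mean excess was at least 1. Its 10 leading genes also had to hold no more markers of any other class than of its own. A cluster with a median UMI count under 1/3 of the library's needed at least 1 own marker among them. The condition on leading genes kept a name from cluster 3 of D7 (1600 cells). The bound on the mean was set after the first clusterings were seen. Without it 1 more cluster with 9.03% of cells in D7 and 4 more with 15.8% of cells in D17 would have had a name. Names are written as "-like" because they rest on marker lists. A class's own markers being higher in it follows from the naming and is identity, not a result.

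With 1 library per group no test between groups was possible, and cells of 1 library are not replicates. UMIs were summed over the cells of a group, and ratios of CPM were taken for genes with at least 100 UMIs over the cells compared. Groups differed in total UMIs, so a scarce gene passes this filter more easily where it is higher in the group with more UMIs. Ratios carry exact conditional binomial 95% intervals and shares carry exact Clopper-Pearson intervals. Intervals cover counting error only. A class without a cluster has a share of 0 by the naming rule, which sets no limit on how many such cells were present. The median log2 ratio of each of 27 gene lists and of the marker lists was given where at least 3 members were measured, with an interval from 1000 Poisson draws, and set against 10000 random lists matched on expression in 20 bins. The placements among random lists are not given below, so lists are described by size alone. Differences of at least 2-fold were counted as higher or lower. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.

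Named genes were chosen by a fixed rule. From each list described these were up to 4 members with at least 100 UMIs, those with the largest ratios in size and the member furthest the other way. From each comparison these were the 10 genes furthest up and the 10 furthest down with at least 50 CPM in the higher group. Genes without a symbol and mitochondrial and ribosomal protein genes were left out of these. The 10 genes POU5F1, SOX2, NANOG, GATA6, SOX17, GATA3, CDX2, TBXT, ISL1 and CGA were looked up in every class. The lists, this rule, the filters, the clustering settings and the comparisons over all cells and within epiblast-like and hypoblast-like cells were set before the data were examined. The comparisons within amnion-like and mesenchyme-like cells, both with at least 50 cells per library, were added after.

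The ratios were tested on simulated data, Poisson draws from the D7 profile at the depth of each library with 200 genes changed, which hold counting error and no spread between libraries. For genes changed 2-fold the median log2 ratio found was 0.99 over all cells and 1.03 in epiblast-like cells, and for genes changed 4-fold 1.99 over all cells and 1.98 in hypoblast-like cells. Intervals held the true ratio for 95.6% of unchanged genes over all cells, 96.2% in epiblast-like and 95.7% in hypoblast-like cells, and for 91.5% to 98.9% of changed genes. Every changed gene had the right direction.

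Alternatives were other Leiden resolutions (0.3 and 1), clustering of both libraries jointly, no cell filter, at least 2000 genes per cell, doublets kept, no filter on low counts, equal weight per cell, thinning to 1000 UMIs per cell, and scale factors of edgeR 4.0.16 (TMM) and DESeq2 1.42.0 run in R 4.3.3. These tools gave scale factors and no test. The joint clustering made no correction between the libraries beyond scaling each cell to 10000 counts. Removing the cells of highest doublet score, 1268 in D7 and 828 in D17 at a nominal 0.8% of doublets per 1000 cells, leaving out clusters without a name, and dropping the condition on leading genes or the bound on the mean excess were added after the data were seen.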

Results

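Single-cell RNA was counted in blastoids of the cynomolgus macaque, which are embryo-like structures grown from stem cells. The series holds 2 libraries. The library labelled D7 came from blastoids and the library labelled D17 from blastoids cultured further. Each group had 1 library, so no spread between replicates could be measured and no test between groups was made. Differences are called by size, at least 2-fold, and every 95% interval covers counting error only. The deposited counts held 41929809 UMIs (unique molecules counted) for D7 and 90695313 UMIs for D17. After filtering, 12485 cells with a median of 2153 UMIs were kept for D7, 75.2% of its barcodes. For D17, 9945 cells with a median of 7657 UMIs were kept, 93.5% of its barcodes. Expression is given as CPM, the UMIs of a gene summed over a group of cells and scaled to a common total per group.

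The question for the library labelled D7 is which cell types the blastoids held. Cells with collagen-rich profiles like extraembryonic mesoderm or mesenchyme (mesenchyme-like from here) made up 25.3% of kept cells (24.6 to 26.1; exact Clopper-Pearson intervals throughout). Amnion-like cells made up 14.5% (13.9 to 15.1), and cells like hypoblast or visceral endoderm, the yolk sac lineage (hypoblast-like from here), 8.22% (7.74 to 8.71). Epiblast-like cells, the lineage that forms the embryo proper, made up 3.95% (3.61 to 4.31). No cluster took the name of trophoblast, primitive streak, germ cells or endothelium. The smallest cluster held 85 cells (0.681%), so smaller groups of cells could have gone without a cluster of their own. With both libraries clustered jointly, 16 cells of D7 were endothelium-like (0.128%), 12 germ cell-like (0.0961%) and 3 streak-like, and 0 trophoblast-like. That clustering made no correction between the libraries. The other 48.1% (47.2 to 48.9), in 6 of 11 clusters, were left without a name by the naming rule. These clusters were also split further at a resolution of 1. A part of cluster 7 with 118 cells scored best on the endothelium list (4 markers, mean excess 0.907). Parts scoring best on the streak list included 1 of cluster 3 with 199 cells (5 markers, mean excess 0.983). Both missed the bound of 1 on the mean excess.

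Epiblast-like cells of that library led with pluripotency genes. NANOG was 18.4-fold higher there than in the other cells (56.9 against 3.09 CPM), SOX2 was 14.1-fold higher, and DPPA5, a gene of early pluripotent cells, 20.7-fold higher. Of 10 measured epiblast markers, 7 were at least 2-fold higher and NODAL had 2 UMIs (log2 ratio -1.80, interval -4.85 to 0.07). In the hypoblast-like cells all 13 measured plasma protein genes were at least 2-fold higher, with a median log2 ratio of 3.80. APOC3 stood at 446 against 23.7 CPM and TTR, the thyroid hormone carrier, at 9048 against 569 CPM. Amnion-like cells had VTCN1 at 162 against 18.8 CPM and 10 of 13 epithelial adhesion genes at least 2-fold higher (median 1.27). CDH1, which joins epithelial cells, was 6.87-fold higher. Trophoblast markers were also higher in these cells (median 1.67, 5 of 8 at least 2-fold higher), led by TACSTD2, KRT7 and GATA3, while PAGE4 was lower (log2 ratio -3.10). Mesenchyme-like cells carried COL3A1 at 6739 against 616 CPM and POSTN at 1337 against 89.3 CPM. All 9 measured posterior HOX genes, which pattern the rear of the body axis, were at least 2-fold higher in them (median 2.44), with HOXC8 14.0-fold higher.

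Among the clusters without a name in that library, cluster 9 (323 cells, 2.59%, interval 2.32 to 2.88) was led by heart muscle genes. MYH6, an atrial myosin, stood at 3309 against 18.6 CPM in the other cells, the sarcomere gene TTN at 7529 against 57.3 CPM and the atrial light chain MYL7 at 9570 against 102 CPM. Cluster 3 (1600 cells) was led by GSC, a gene of the organiser, at 131 against 12.2 CPM, and by HHEX at 144 against 21.2 CPM. In it 6 of 8 definitive endoderm genes were at least 2-fold higher (median 2.26), and so were 10 of 14 hypoblast markers (median 1.25). Hypoblast was the best list of this cluster (11 markers, mean excess 1.09), and it stayed without a name because its leading genes held more markers of another class.

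These shares depended on the clustering and on the naming. With the condition on leading genes dropped, an alternative added after the data were seen, cluster 3 counted as hypoblast-like and that class made up 21.03%. With the condition on the mean excess dropped, also added after, it made up 17.3%. At a Leiden resolution of 0.3, which makes fewer clusters, amnion-like cells made up 31.7%, hypoblast-like cells 21.1% and epiblast-like cells 0%. With both libraries clustered jointly, epiblast-like cells made up 0.120% and amnion-like cells 36.9%. With at least 2000 genes per cell, amnion-like cells made up 21.9% and hypoblast-like cells 18.8%.

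**Figure D1:**
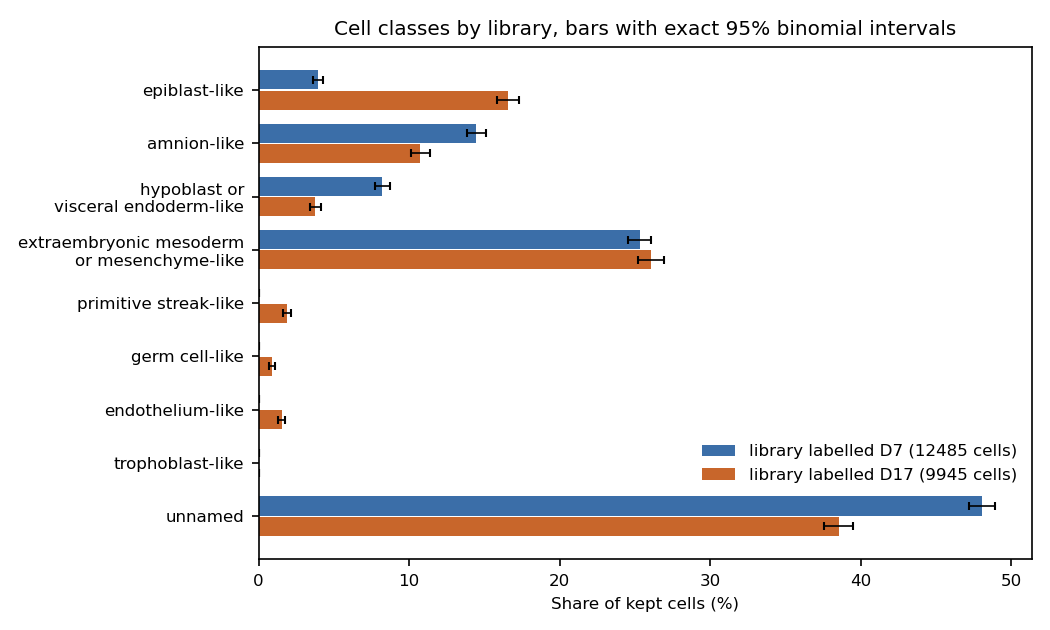
Share of kept cells in each class (horizontal axis, percent) for the library labelled D7 and the library labelled D17, 1 library each. Bars end at the share and whiskers are exact 95% binomial intervals. Epiblast-like cells made up 3.95% in D7 and 16.6% in D17.

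The question for the library labelled D17 is which cell types were present after longer culture. Epiblast-like cells made up 16.6% (15.9 to 17.3), amnion-like cells 10.7% (10.1 to 11.4), hypoblast-like cells 3.78% (3.41 to 4.17) and mesenchyme-like cells 26.1% (25.2 to 27.0). A streak-like cluster, with genes of the primitive streak where gastrulation starts, made up 1.86% (1.60 to 2.15). Endothelium-like cells made up 1.53% (1.30 to 1.79) and germ cell-like cells 0.865% (0.692 to 1.07). No cluster was named as trophoblast, and the smallest cluster held 86 cells, so a smaller group could have been missed. The clusters without a name, 5 of 18, held 38.5% (37.6 to 39.5). The largest, cluster 0 (2263 cells, 22.8%), had POU5F1 at 499, COL3A1 at 1433 and APOA1 at 1101 CPM. TTR was among its leading genes, and 1 marker of its best list had an excess of at least 1.

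In the streak-like cells MESP1, an early mesoderm factor, stood at 1392 against 18.5 CPM in the other cells, MIXL1 at 751 against 17.2 CPM and TBXT (brachyury) at 92.4 against 3.12 CPM. Of 13 primitive streak markers, the list that gave the cluster its name, 12 were at least 2-fold higher (median 3.06). Of 11 embryonic mesoderm markers, 7 were at least 2-fold higher (median 3.25), while MEOX1 had 1 UMI (log2 ratio -2.53, interval -7.85 to -0.04). Germ cell-like cells had NANOS3, which marks primordial germ cells, at 136 against 1.59 CPM, and 6 of 7 germ cell markers at least 2-fold higher. POU5F1 was higher in them as well (3241 against 403 CPM), whereas SOX2 was lower (log2 ratio -2.35) and 11 of 14 primed pluripotency genes were at least 2-fold lower (median -2.06), OTX2 among them. Endothelium-like cells had CDH5, a junction protein of vessels, at 349 CPM, 175-fold higher than in the other cells, and 10 of 11 endothelium markers at least 2-fold higher (median 6.88). Of 5 erythroid markers measured there, 3 were at least 2-fold higher (median 2.24), TAL1 and HBE1 among them.

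Epiblast-like cells of this library had SOX2 at 328 against 13.3 CPM, and all 13 measured epiblast markers were at least 2-fold higher (median 3.05). FGF2 and SFRP2 were among 9 of 14 primed pluripotency genes at least 2-fold higher (median 1.17). Amnion-like cells led with GABRP, 29.1-fold higher at 82.3 CPM, and TFAP2B, 21.6-fold higher. Epithelial adhesion genes were higher in them (median 1.62, 11 of 13 at least 2-fold). Of 9 trophoblast markers, 6 were at least 2-fold higher (median 1.32). CDX2 was higher as well (log2 ratio 1.11), but lower at a resolution of 1.0 (-0.46). It stood at 248 CPM in cluster 8 (386 cells) and at 43.0 CPM in cluster 4 (683 cells) of this class. These were split, with the parts of both scored against the same mean. Then 0 of 7 parts of cluster 8 and 8 of 9 parts of cluster 4 took the amnion-like name. The parts enter the mean they are scored against, which lowers their excess on a shared list. The amnion-like cluster 1 of D7, split alike, had 3 of 9 parts with the amnion-like name (237, 135 and 70 of 1806 cells). A part with 212 cells scored best on the epiblast list, as did parts of cluster 8 of D17 with 49 and 47 cells. Hypoblast-like cells had APOB, the lipoprotein scaffold, at 928 against 10.1 CPM, and all 14 measured plasma protein genes were at least 2-fold higher (median 5.68). Definitive endoderm genes were all at least 2-fold higher there (8 of 8, median 3.95), SOX17 at 197 against 8.62 CPM. Mesenchyme-like cells had COL1A2 at 3838 against 474 CPM, immediate early genes higher (median 1.67, 7 of 10 at least 2-fold) and 17 of 18 cell cycle genes at least 2-fold lower (median -1.53). Mesenchyme was also the best list of clusters 6 (523 cells), 7 (485 cells, led by H1-3) and 12 (346 cells, led by ASPM), which the bound on the mean excess left without a name (0.505, 0.617 and 0.665). Without that bound the mesenchyme-like share was 39.7% and the cell cycle median -0.40. The hypoblast-like share was then 5.94%, and posterior HOX genes in that class turned from -1.42 to 0.38 and ISL1 from -1.37 to 1.56.

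Depth of the cells differed between these classes, from a median of 5732 UMIs in epiblast-like to 14715 in streak-like cells, and 1 epiblast-like cluster of 101 cells had a median of 20767 UMIs, with 96.0% of its cells among the highest doublet scores. No hypoblast-like cluster was named with at least 2000 genes per cell (0%), joint clustering left 0.0101%, and a resolution of 0.3 gave 6.01%. The streak-like share was 3.42% with at least 2000 genes.

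**Figure D2:**
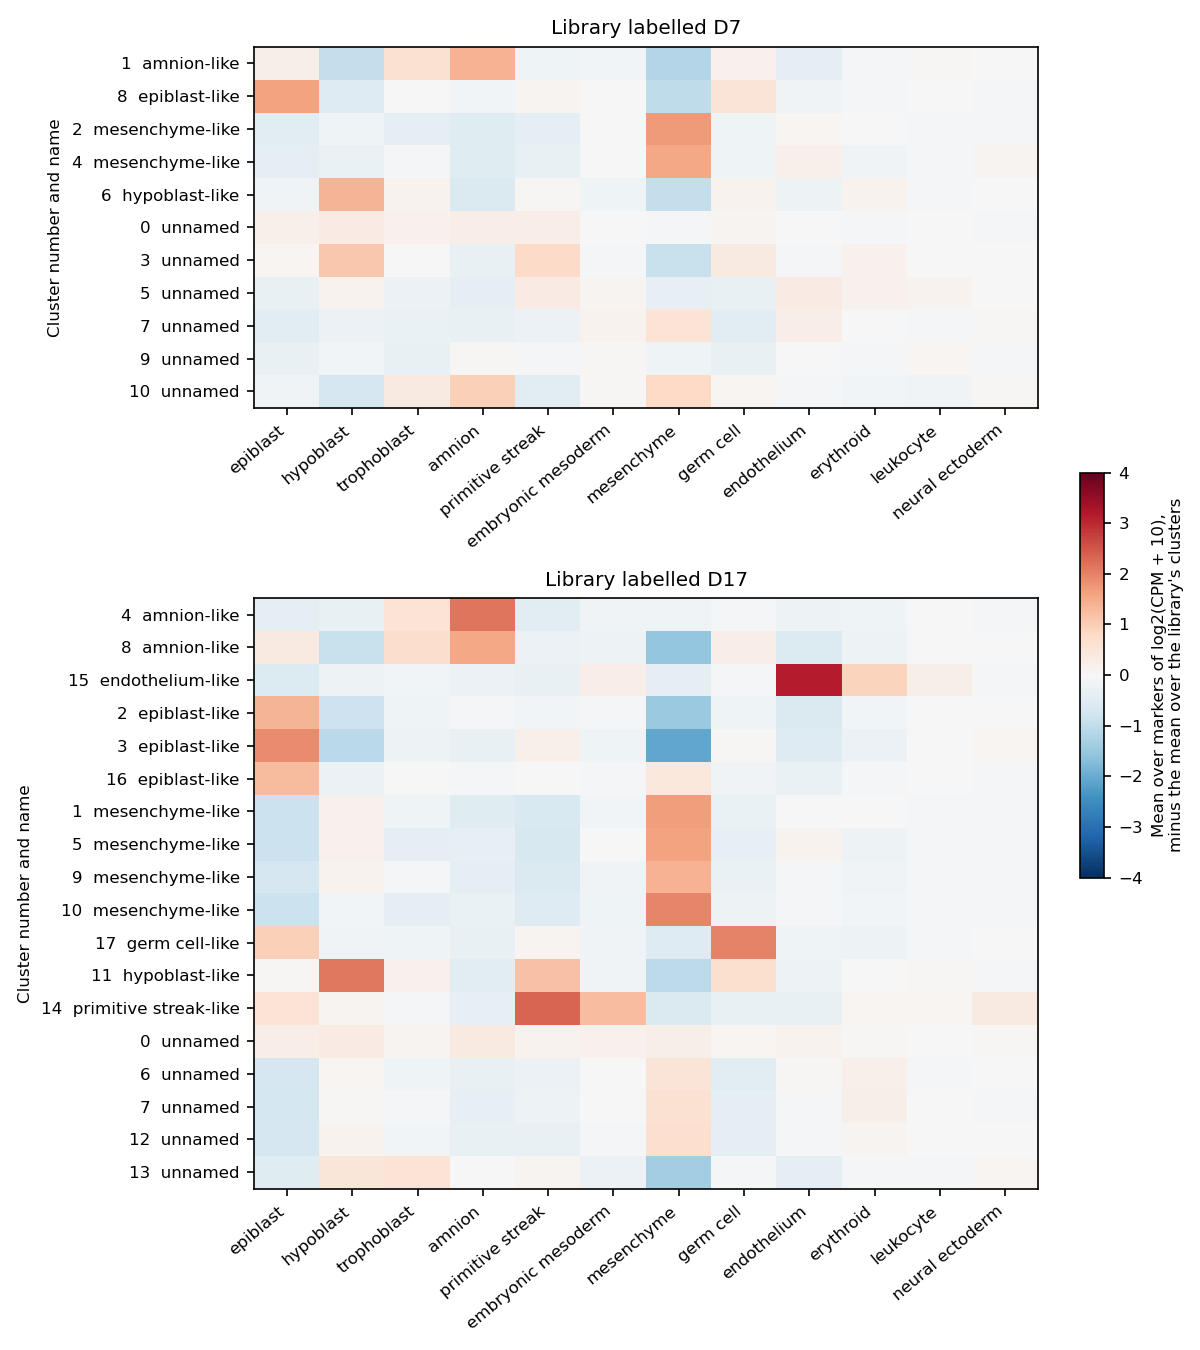
Mean excess of each marker list (columns) in each cluster (lines) of the 2 libraries, as log2(CPM + 10) minus the mean over the library's clusters. Red is higher and blue lower. Streak, germ cell and endothelium names of whole clusters appear in the library labelled D17 alone. On splitting, parts of clusters 7 and 3 of D7 scored best on the endothelium and streak lists. Cluster 9 of D7 stands out on none of the lists shown, and none of them is of heart muscle.

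Over all kept cells, the question is which genes differed between the further cultured blastoids and the earlier ones. Epiblast markers were higher in D17 (median log2 ratio 1.20, interval 1.17 to 1.27, 11 of 14 at least 2-fold), with POU5F1 at 428 against 184 CPM and NANOG at 15.6 against 4.88 CPM. Posterior HOX genes were higher (median 2.16, interval 2.05 to 2.33, 12 of 13 at least 2-fold), HOXA7 at 14.2 against 1.25 CPM, and so were 6 of 9 anterior HOX genes (median 2.06). Endothelium markers (median 2.01, 8 of 11) and primitive streak markers (median 1.04, 7 of 13) were higher too, with CDH5 at 8.07 against 0.961 CPM and TBXT at 6.04 against 0.597 CPM. Plasma protein genes were lower (median -1.53, interval -1.58 to -1.47, 8 of 14 at least 2-fold lower and 2 higher), APOA1 7.53-fold and TTR 9.79-fold, while the fibrinogen chain FGG was 25.1-fold higher.

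The genes furthest up in D17 included MESP1 (38.8-fold, 63.5 against 1.64 CPM), the collectin COLEC10 (18.1-fold), CDX2 (5.08-fold) and PGF, a placental growth factor (4.86-fold). The linker histones H1-3 and H1-4 stood among them as well, H1-3 at 772 against 52.0 CPM and H1-4 at 316 against 53.9 CPM. Those furthest down included MYH6, with 3 UMIs in D17 against 4802 in D7 (log2 ratio -11.87, interval -14.15 to -10.32), STMN2 (145-fold), the iron hormone HAMP (92.1-fold), MYL3 (28.3-fold), ACTC1 (19.5-fold), TUBB3 (13.0-fold) and the hormone SST (11.7-fold). The wider cardiac list had a median of -0.33, 4 of 12 genes at least 2-fold lower, and HAND1 stood at a log2 ratio of 0.79. SOX17 was lower (-1.12). Under 2-fold were GATA6 (-0.94), ISL1 (-0.07) and GATA3 (-0.42), and CGA, the chorionic gonadotropin alpha chain, was at 15.4 against 9.11 CPM.

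Of the metabolic lists, cholesterol synthesis was lower in D17, with a median of -1.002 and 8 of 15 genes at least 2-fold lower, INSIG1 and HMGCS1 among them, and FDPS at -0.09. Hypoxia genes (median -0.81) and glycolysis genes (median -0.49) stayed under 2-fold as lists, with 5 of 12 and 6 of 18 genes at least 2-fold lower, NDRG1 by 6.48-fold and LDHA by 2.67-fold, and ANKRD37 higher (log2 ratio 1.26). Cell cycle genes had a median of 0.47 with 0 of 18 past 2-fold in either direction. Trophoblast markers had a median of 0.06 over 9 genes. Over all 15286 genes compared the median was 0.11, and 1164 genes were at least 2-fold higher and 1343 at least 2-fold lower by count, with no test behind these numbers.

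Sums over all cells mix the make-up of a library with expression in its cells. With each cell thinned to 1000 UMIs, the medians were 0.43 for streak and 1.05 for endothelium markers. With clusters without a name left out, an alternative chosen after the data were seen, they were 1.98 for streak markers and 1.37 for posterior HOX genes, and streak markers stood at 0.60 when each cell weighed equally.

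**Figure D3:**
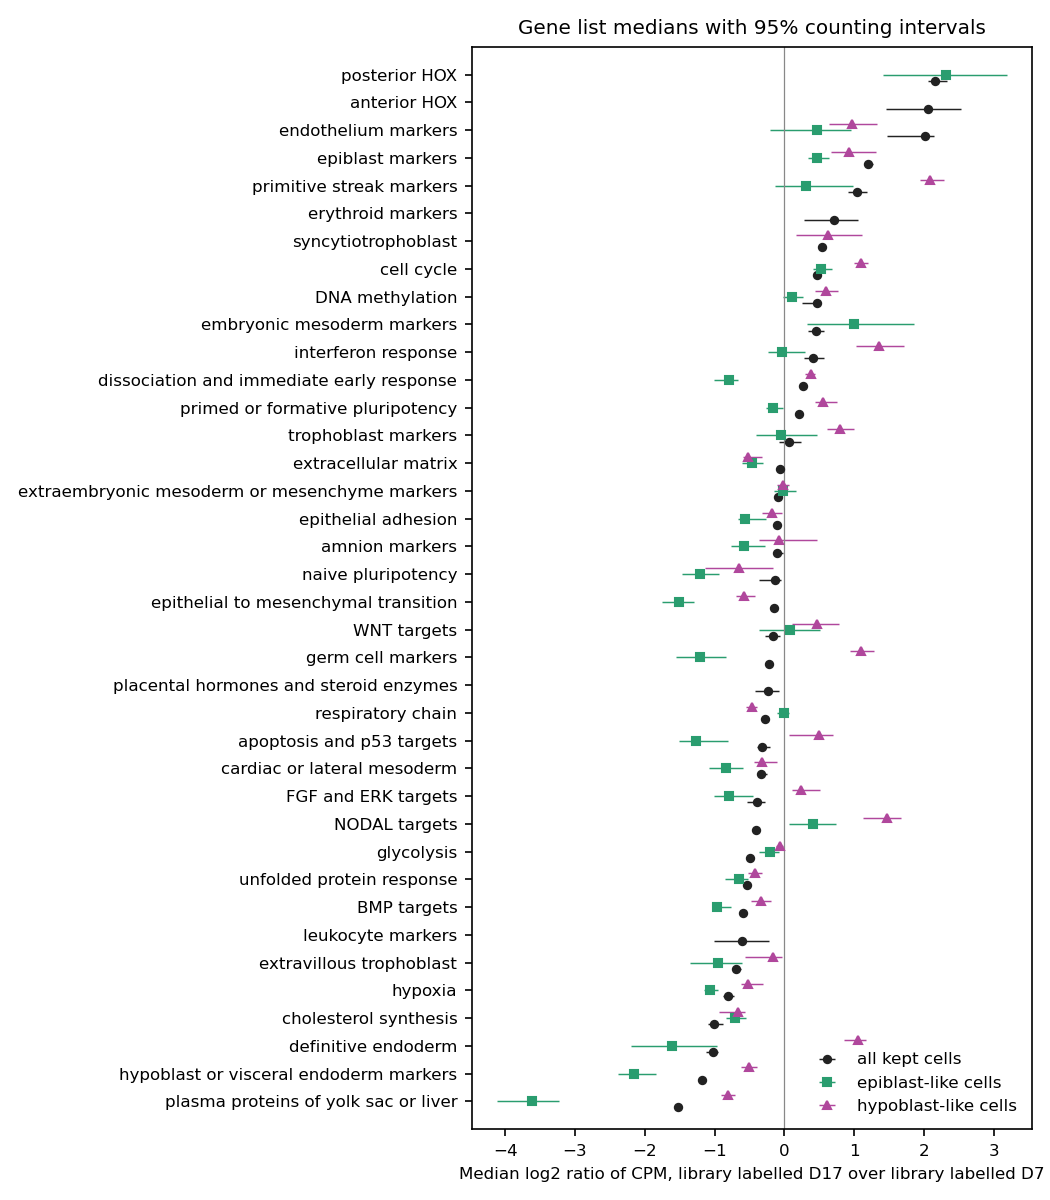
Median log2 ratio of CPM, D17 over D7, of each gene list (vertical axis) over all kept cells, epiblast-like cells and hypoblast-like cells. Points are medians and lines 95% counting intervals, and a list without a point had under 3 measured genes. Posterior HOX genes stand at 2.16 over all cells and plasma proteins at -1.53.

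Within epiblast-like cells, the question is whether pluripotent cells differed between the libraries. The classes were named in each library apart, and with both clustered jointly 15 cells of D7 and 1637 of D17 were epiblast-like, so a match of the cells compared is not shown. The joint clustering made no correction between the libraries, which differ in depth, so these counts do not exclude a match either. Their core genes differed by less than 2-fold, with POU5F1 at 1285 against 1013 CPM, SOX2 at 328 against 275 CPM and NANOG at 67.1 against 56.9 CPM. Epiblast markers had a median of 0.47 (interval 0.34 to 0.63), 2 of 13 at least 2-fold higher, VRTN and TDGF1. The WNT inhibitor SFRP1 stood at 1165 against 163 CPM, NNAT was 5.57-fold higher, and H1-3 was 10.1-fold higher. All 5 measured posterior HOX genes were at least 2-fold higher (median 2.31) at low levels. The other genes of this list had under 100 UMIs over the cells compared. The D17 cells held 14566029 UMIs against 1282541 in D7, so a scarce gene passes this filter more easily where it is higher in D17. That every measured gene was higher can therefore come partly from the filter. HOXC8 had 3 UMIs in D7 (log2 ratio 2.43, interval 0.86 to 4.72). In D17 HOXC8 stood at 62.9 CPM in cluster 16, and at 6.24 and 3.20 CPM in the epiblast-like clusters 2 and 3. Of the 101 cells of cluster 16, 96.0% were among the highest doublet scores, so the size of this rise depends on that cluster. Cell cycle genes had a median of 0.53, MKI67 at 373 against 170 CPM.

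Lower in the D17 epiblast-like cells were genes of epithelial to mesenchymal transition (median -1.51, 4 of 8 at least 2-fold lower), FN1 8.60-fold and VIM 4.95-fold. So were p53 targets (median -1.27, 5 of 9), GADD45A 7.01-fold, and hypoxia genes (median -1.06, 6 of 11), NDRG1 17.5-fold, while ANKRD37 was 4.73-fold higher. Immediate early genes had a median of -0.79 with 4 of 10 at least 2-fold lower, and genes of the unfolded protein response -0.65 with 3 of 10. KHDC3L, an oocyte and early embryo gene, was 22.1-fold lower, and of the naive pluripotency genes DPPA5 was 5.78-fold lower and ZFP42 8.32-fold higher. Plasma protein genes stood lowest (median -3.61, 7 of 7), APOA1 at 49.2 against 2101 CPM and TTR at 8.17 against 511 CPM. In D7 those genes were found in every cluster. Outside the hypoblast-like cluster and the clusters 0 and 3, which have no name, their median level was 3.71% to 7.94% of the hypoblast-like one. The mesenchyme marker COL3A1 was also found in every D7 cluster, at 412 CPM in the epiblast-like one. In the D17 epiblast-like clusters it stood at 115 to 1909 CPM. Whether RNA of other cells counts in the ratios of FN1, VIM or the other lists here was not tested.

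Primed pluripotency genes had a median of -0.16, but of 0.02 to 0.42 under 4 alternatives, so no direction was seen. Epiblast-like cells of D7 were shallow, 493 cells with a median of 1522 UMIs against 1650 cells with 5732 in D17, and with all cells thinned to 1000 UMIs the plasma protein median was -5.10.

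Within hypoblast-like cells, the question is the same for the yolk sac lineage. With joint clustering 913 cells of D7 and 1 of D17 were hypoblast-like, so here too a match of the cells is not shown. Without a correction between libraries these counts do not exclude a match either. Cell cycle genes were higher in D17 (median 1.09, 13 of 18 at least 2-fold), MKI67 at 350 against 98.6 CPM. Genes of anterior and definitive endoderm were higher (median 1.06, 5 of 8), CXCR4 3.84-fold and HHEX 2.32-fold, and so were streak markers (median 2.09, 5 of 6), with FGF17 at 266 against 6.83 CPM and GSC 12.3-fold higher at 136 CPM. NODAL targets had a median of 1.46, GDF3 4.62-fold higher, whereas CER1 stood at a log2 ratio of -0.72. In D7, GSC (131 CPM) and HHEX (144 CPM) were among the leading genes of cluster 3, outside the D7 class. With cluster 3 counted as hypoblast-like, the medians were 1.26 for streak markers, 0.62 for definitive endoderm genes and 0.66 for NODAL targets, and the log2 ratios 3.11 for FGF17 and 1.24 for GSC. Interferon response genes (median 1.35, 4 of 7) included MX1, 28.2-fold higher, and ISG15, 12.3-fold higher.

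Plasma protein genes went both ways in these cells. Their median was -0.80 (interval -0.91 to -0.70) and their mean 0.10, with 6 of 14 at least 2-fold lower and 4 at least 2-fold higher. TTR stood at 2362 against 9048 CPM and APOA1 at 10308 against 27377 CPM, while FGG was 96.4-fold and FGA 6.44-fold higher. HAMP was 36.9-fold lower, and SST and NPPB were lower as well. H1-3 was 31.9-fold higher. The 376 cells of D17 had a median of 10184 UMIs and the 1026 of D7 had 4142. The cell cycle median was 0.91 with edgeR factors, 0.95 with DESeq2 factors and 0.995 at a resolution of 1. It was 0.84 with cluster 3 counted in and 0.56 without the bound on the mean excess, where the plasma protein medians were -0.38 and -0.53.

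Within amnion-like cells, a comparison added after the data were seen, all 9 measured posterior HOX genes were at least 2-fold higher in D17 (median 2.43, interval 2.08 to 3.03), HOXD9 at 19.3 against 1.40 CPM. All 5 measured anterior HOX genes were too (median 1.69), HOXD4 19.8-fold. CDX2 stood at 130 against 20.7 CPM, HEY1 at 311 against 48.5 CPM and the growth factor HGF at 70.2 against 11.9 CPM. In D17 CDX2 stood at 248 CPM in cluster 8 and at 43.0 CPM in cluster 4. On splitting, 3 of 9 parts in D7 kept the amnion-like name. In D17 most parts of cluster 4 and 0 of 7 parts of cluster 8 kept it. The parts enter the mean they are scored against, which lowers their excess on a shared list. Lost names alone therefore do not show whether a cluster was uniform. Parts of clusters 4 and 8 were scored against the same mean, so differences between these clusters do not come from it. In cluster 8, parts with 49 and 47 cells scored best on the epiblast list. Parts with 70 and 34 cells scored best on the trophoblast list, and the rest on the amnion list. Amnion markers had a median of 0.43, TFAP2B 3.98-fold higher, and extracellular matrix genes of 0.67, COL3A1 at 662 against 206 CPM and FN1 lower (log2 ratio -1.09). Mesenchyme markers had a median of 0.93, 5 of 11 at least 2-fold higher. COL3A1 stood at 1027 CPM in cluster 4 of D17 and 165 CPM in cluster 8, and a part of cluster 4 with 71 cells (median 15583 UMIs) scored best on the mesenchyme list (9 markers, mean excess 1.60). Cholesterol synthesis genes were lower (median -1.48, 12 of 15 at least 2-fold), HMGCS1 3.85-fold and LDLR 3.76-fold. Plasma protein genes were lower (median -2.72, 7 of 8), APOA1 at 49.1 against 1349 CPM. In the D7 amnion-like cluster the list's median level was 4.68% of the hypoblast-like one, within the range of the other D7 clusters.

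Within mesenchyme-like cells, also compared after the data were seen, immediate early genes were higher in D17 (median 1.47, interval 1.41 to 1.56, 7 of 10 at least 2-fold). FOS stood at 1262 against 108 CPM and EGR1 at 413 against 62.2 CPM. This set is known to respond to the enzymes used to part cells. Its median was -0.79 in epiblast-like, 0.01 in amnion-like and 0.37 in hypoblast-like cells of the same libraries. Posterior HOX genes (median 1.21, 9 of 13) were higher, HOXA13 5.34-fold, and COLEC10 was 31.4-fold higher. Of p53 targets 3 of 11 were at least 2-fold higher (median 0.67), CDKN1A among them. STMN2 was 333-fold lower, SST 13.0-fold lower at 103 CPM, and WFDC2 8.99-fold lower. Cholesterol synthesis genes were lower (median -1.13, 8 of 15). Cell cycle genes had a median of -0.48, 3 of 18 at least 2-fold lower, UBE2C 5.41-fold, with MCM3 at 0.26. Without the bound on the mean excess, which takes in clusters 6, 7 and 12 of D17, the cell cycle median turned to 0.44 and the immediate early median was 0.98, so no direction of cell cycle genes was settled. Extracellular matrix genes had a median of 0.02. Plasma protein genes were lower (median -3.13, 9 of 11), APOA1 at 74.9 against 1470 CPM, where the list in the D7 mesenchyme-like clusters stood at 4.72% and 5.12% of the hypoblast-like level.

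Scaling shifted the within-class ratios. The edgeR factors moved all log2 ratios by 0.13 in epiblast-like, -0.19 in hypoblast-like, -0.14 in amnion-like and -0.08 in mesenchyme-like cells.

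**Figure D4:**
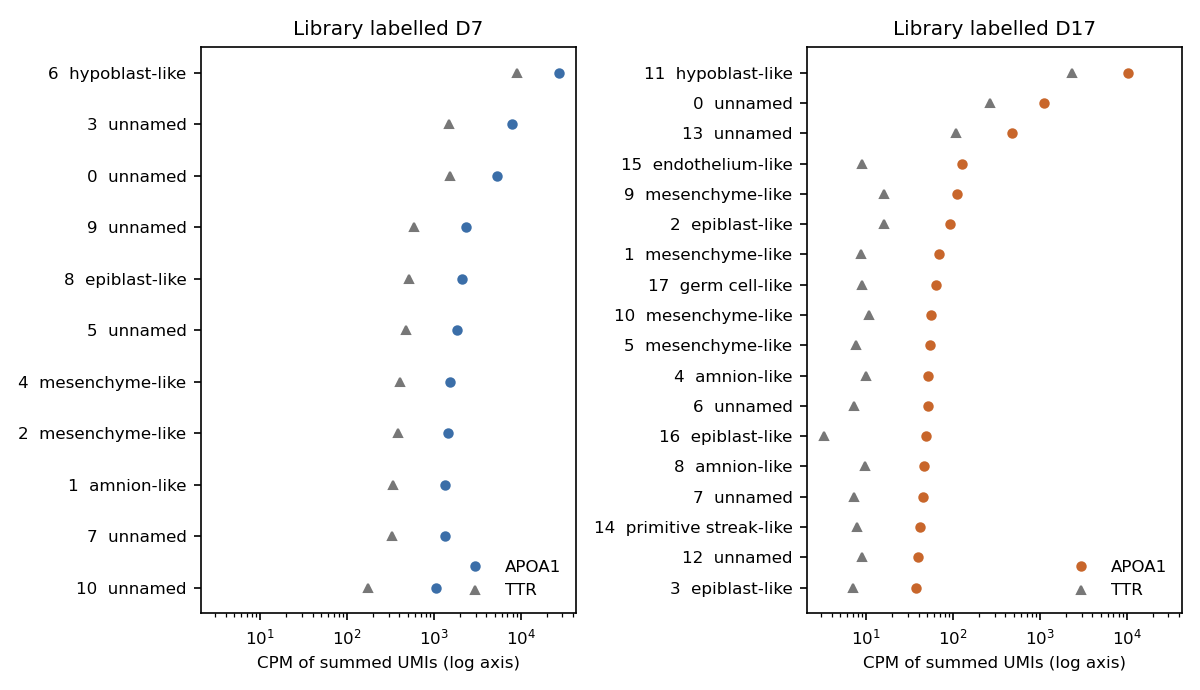
Level of APOA1 and TTR in each cluster (vertical axis) of each library, as CPM of summed UMIs on a log axis. In D7 APOA1 stood between 1040 and 27377 CPM in all 11 clusters, and in D17 its lowest level was 37.3 CPM.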

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

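The removal of cells of highest doublet score, the leaving out of clusters without a name, and the dropping of the naming conditions on leading genes and on the mean excess were alternatives added after the data were seen. No paired analysis was possible because each group had 1 library, both numbered replicate 1. Of 236 comparisons of a leading result with an alternative, 140 stayed within the counting interval, 96 moved and 0 reversed. Reversed means that a value of at least 2-fold changed sign. A class share has no sign, so it could only stay or move, also where it fell to 0%. The 0 therefore speaks only for ratios of at least 2-fold. Of the 96, 4 also changed sign from a main value under 2-fold, all of primed pluripotency genes in epiblast-like cells (main value -0.16). Of 5883 for single genes and other lists, 4736 stayed, 1140 moved, 130 of these with a change of sign from under 2-fold, and 7 reversed. The cause was not tested in any of these. Counting intervals are narrow, so a small move counts. Shares are percent of cells, and other values are median log2 ratios of D17 over D7 unless said otherwise.

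With the doublet marked by Scrublet kept, D7 epiblast-like cells made up 4.71% and amnion-like cells 13.5%. Primed pluripotency genes in epiblast-like cells stood at 0.016. This setting adds 1 cell, which cannot by its own count move a share so far. Clustering the cells anew thus moved shares by more than the counting intervals cover. With cells of highest doublet score removed, D7 had 5.88% epiblast-like and 12.9% amnion-like cells. D17 had 9.92% amnion-like, 5.62% hypoblast-like, 27.9% mesenchyme-like and 1.23% endothelium-like cells. Plasma protein genes were then at -1.44 over all cells and -1.09 in hypoblast-like cells, cell cycle genes in hypoblast-like cells at 1.28, and primed pluripotency genes in epiblast-like cells at 0.42.

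With at least 2000 genes per cell, D7 had 2.95% epiblast-like, 21.9% amnion-like, 18.8% hypoblast-like and 26.4% mesenchyme-like cells. D17 had 11.8% epiblast-like, 9.34% amnion-like, 0% hypoblast-like, 30.2% mesenchyme-like and 3.42% streak-like cells. Over all cells, streak markers were at 1.51, endothelium markers at 1.45, plasma protein genes at -1.42 and cardiac genes at -0.22. Primed pluripotency genes in epiblast-like cells were at 0.12 and immediate early genes in mesenchyme-like cells at 1.61. Here 2 lists reversed, naive pluripotency genes in amnion-like cells from -1.12 to 0.56 and streak markers in mesenchyme-like cells from -1.84 to 0.46.

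At a Leiden resolution of 0.3, D7 had 0% epiblast-like, 31.7% amnion-like and 21.1% hypoblast-like cells, and D17 6.01% hypoblast-like and 31.4% mesenchyme-like cells. At a Leiden resolution of 1, D7 had 5.42% epiblast-like and 11.99% amnion-like cells, and D17 12.7% epiblast-like, 7.67% amnion-like and 2.48% streak-like cells. In epiblast-like cells primed pluripotency genes were then at 0.36 and plasma protein genes at -3.15, and cell cycle genes in hypoblast-like cells at 0.995. Against the other cells of D17, epithelial adhesion genes in amnion-like cells were at 1.35, plasma protein genes in hypoblast-like cells at 5.81, and CDX2 in amnion-like cells reversed from 1.11 to -0.46. With joint clustering, D7 had 0.120% epiblast-like, 36.9% amnion-like and 7.31% hypoblast-like cells. D17 had 0.0101% hypoblast-like, 34.7% mesenchyme-like and 2.62% streak-like cells. With no cell filter, D7 had 12.2% amnion-like and 18.4% mesenchyme-like cells. D17 had 21.95% epiblast-like, 9.999% amnion-like, 3.355% hypoblast-like and 24.4% mesenchyme-like cells.

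With the condition on leading genes dropped, D7 had 21.03% hypoblast-like cells. In hypoblast-like cells plasma protein genes were then at -0.38 and cell cycle genes at 0.84, and against the other cells of D7 plasma protein genes were at 3.43. With the condition on the mean excess dropped, D7 had 17.3% and D17 5.94% hypoblast-like cells, and D17 39.7% mesenchyme-like cells. Plasma protein genes in hypoblast-like cells were then at -0.53, and against the other cells at 3.002 in D7 and 5.05 in D17. Cell cycle genes in hypoblast-like cells were at 0.56 and immediate early genes in mesenchyme-like cells at 0.98. Cell cycle genes in mesenchyme-like cells turned from -0.48 to 0.44. Against the other cells of D17, posterior HOX genes and ISL1 in hypoblast-like cells reversed from -1.42 to 0.38 and from -1.37 to 1.56, and erythroid markers in mesenchyme-like cells from -1.09 to 0.021.

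With the mean over cells, epiblast markers over all cells were at 1.001, streak markers at 0.60, plasma protein genes at -1.60 and cardiac genes at -0.24. Plasma protein genes in hypoblast-like cells were at -0.92 and immediate early genes in mesenchyme-like cells at 1.33. With no low count filter, plasma protein genes over all cells were at -1.67, and embryonic mesoderm markers in amnion-like cells reversed from 3.30 to -0.70. Thinned to 1000 UMIs per cell, the libraries gave 1.07 for epiblast markers over all cells, 0.43 for streak markers, 1.05 for endothelium markers, -1.59 for plasma protein genes, 2.02 for posterior HOX genes and -0.41 for cardiac genes. Plasma protein genes were then at -5.10 in epiblast-like and -0.98 in hypoblast-like cells, cell cycle genes in hypoblast-like cells at 1.23, and immediate early genes in mesenchyme-like cells at 1.35.

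With clusters without a name left out, epiblast markers over all cells were at 1.34, streak markers at 1.98, endothelium markers at 2.27, plasma protein genes at -1.59, posterior HOX genes at 1.37 and cardiac genes at -0.14. With edgeR factors, plasma protein genes in hypoblast-like cells were at -0.99, cell cycle genes there at 0.91, and immediate early genes in mesenchyme-like cells at 1.39. With DESeq2 factors these were at -0.95, 0.95 and 1.39. The DESeq2 factors shifted all log2 ratios by 0.13 in epiblast-like, -0.15 in hypoblast-like, -0.15 in amnion-like and -0.08 in mesenchyme-like cells.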

Other observations

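The tests of free RNA, of the depth of heart muscle cells and of exchanged labels were chosen after the results were seen, and the others before.

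The linker histones H1-3 and H1-4 were higher in the library labelled D17. H1-3 was among the 10 genes furthest up in each of the 5 comparisons, from 7.43-fold in mesenchyme-like to 31.9-fold in hypoblast-like cells, and H1-4 was among them in 4. In D17 a cluster without a name, cluster 7 (485 cells), was led by H1-3 at 3770 against 536 CPM in the other cells, by H1-5 and by H2AC12, and cluster 12 (346 cells) by the mitosis genes ASPM and CENPE.

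Cluster 13 of D17 (215 cells, 2.16%), also without a name, was led by S100P at 101 against 1.52 CPM, AGR3, ZG16 and CDH17, a cadherin of gut epithelium, at 106 against 2.72 CPM. ISL1 stood there at 384 CPM, and 8 of 13 posterior HOX genes were at least 2-fold higher than in the other cells (median 1.57). In D7, cluster 5 (1128 cells) was led by CHL1, NMB and TNC, and cluster 7 (940 cells) by TECRL, TGFB2 and the apelin receptor APLNR. Cluster 10 of D7 (85 cells) had a median of 8360 UMIs and 91.8% of its cells among the highest doublet scores.

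Plasma protein genes were higher in D7 within classes other than the hypoblast-like one, and free RNA from hypoblast-like cells is a candidate explanation. Within the other D7 clusters the list's levels, as ratios to the hypoblast-like cluster, had a median absolute deviation of 0.25 log2 over 102 values, below the 0.5 set for 1 source of RNA. Cluster 10 had 1.02 over 6 genes, cluster 0 stood at 19.7% of the hypoblast-like level, and cluster 3 was left out of this test. Hypoblast-like cells or doublets counted in those classes were argued against, since the 5% of cells with most of these UMIs held at most 15.3% of them. That was in amnion-like cells, near the 15.2% that depth alone would give there. In epiblast-like cells the share was 14.9% against 23.0% by depth, and in mesenchyme-like cells 12.6% against 13.4%. No biological explanation was tested.

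A cluster led by heart muscle genes was found in D7 alone. Lower depth of that cell type in D17 cannot be told apart from its absence by the fixed cardiac list. With cells thinned alike, the list stood at a median log2 ratio of -0.41. Of its 11 genes, 3 were at least 2-fold lower (ACTC1 at -4.28) and 0 at least 2-fold higher. The list cannot decide, because members such as HAND1 and ISL1 were also expressed elsewhere. In D7 HAND1 stood at 392 CPM in cluster 9 and 847 in the amnion-like cluster 1, ISL1 at 79.7 and 173. Kept cells of D17 had the higher median depth (7657 against 2153 UMIs). This list and its bounds replaced a test on the genes leading the cluster, which were chosen from the pattern itself. Exchanged labels of the 2 libraries cannot be told apart from a true difference with 1 library each, although posterior HOX genes were higher in D17 (2.16) and 5 classes beyond the blastocyst stage were named there against 2 in D7. None of the 12 marker lists was of heart muscle, so cluster 9 of D7 could not count among these classes. The culture time that the labels give stays open as an untested difference.

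No trophoblast-like cluster was named in either library. Splitting the amnion-like clusters into 25 parts to look for trophoblast cells hidden within the amnion-like clusters gave 0 parts with that name, and splitting the others into 71 parts of at least 20 cells (smaller ones were not tested) for trophoblast cells hidden within the unnamed clusters gave 0. Both cannot be told apart from absence, because a small trophoblast part could miss the bound on the mean excess. The parts enter the mean they are scored against, which can lower their excess. List members such as ELF5 (27 UMIs) and CCR7 (1 UMI) were also hardly detected in D17. In D17, 2 parts with 104 cells of the amnion-like cluster 8 and 2 parts with 82 cells of cluster 13 scored highest on the trophoblast list (mean excess up to 0.592 and 0.616). In cluster 8's parts CDX2 stood at 278 and 355 CPM and ISL1 at 148 and 153, in cluster 13's CDX2 at 25.1 and 118 and ISL1 at 1027 and 474, with 0 UMIs of CYP19A1.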
